A study of Mus musculus with 86 samples.

How the data were processed

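The series holds 86 mouse samples, of which 58 are RNA libraries: 20 from whole testes at postnatal days 10, 14, 18 and 28 (P10 to P28), 6 from purified spermatocytes and 6 from purified round spermatids of 4-month-old animals, 14 small RNA libraries and 12 small RNA libraries that the labels describe as enriched for piRNA, the last 2 kinds from testes at P10, P14 and P18. In each of them homozygous *Btbd18* knockouts were set against heterozygous animals of the same C57BL/6 × 129/SvJ hybrid background. Groups held 2 or 3 libraries and were taken from the labels alone. A column of the small RNA table has a name unlike the others that gives P18, a heterozygous control and the digit 2. It matches no sample's title, so whether it is replicate 2 is not certain, and it was used as the unnumbered library of the P18 heterozygous group. The other 28 samples, ChIP-seq and ATAC-seq, were not analysed here.

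Per the labels, poly(A) RNA was prepared with a Nextera kit for testes and with a stranded NEBNext kit for purified cells, and small RNA with a size-selected NEBNext kit. The labels of the piRNA-enriched libraries carry the word beta, and how they were enriched is not stated in the labels. Per the submitters' processing notes, RNA-seq reads were handled with cutadapt 1.8.1, TopHat2 2.1, featureCounts of Subread 1.4.6-p3 and Cufflinks on the mouse build mm10, and small RNA reads with TopHat and featureCounts on the same build. Settings for strand, overlapping genes and reads with several matches, and the annotation, are not stated. The authors deposited 5 tables of raw read counts per gene or piRNA locus, with 1 column per library, and these counts were used as deposited. No reads were realigned.

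Every table lists the same 24276 features, of which 214 are piRNA loci by their names: 100 named by chromosome, band and a number, called intergenic below, and 114 named after a gene, called genic below. Another 1121 are miRNA genes. Symbols of 22549 features (92.9%) match the reference gene table of build GRCm38, the build named mm10 above, and coordinates were taken from it. Stages of piRNA loci (pre-pachytene or pachytene) are not given in the tables.

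Depths were 5.82 to 12.3 M counts (M, mega) per testis library, 0.322 to 0.514 M in spermatocytes, 0.194 to 0.543 M in round spermatids, 4.03 to 20.3 M in small RNA and 2.50 to 16.5 M in piRNA-enriched small RNA. After the low-count filter 16334 features were tested in testes (207 loci), 4618 in spermatocytes (111 loci), 6703 in round spermatids (96 loci), 10405 in small RNA (203 loci) and 12858 in piRNA-enriched small RNA (207 loci). The biological coefficient of variation was 0.0901 in testes, 0.314 in spermatocytes, 0.703 in round spermatids, 0.233 in small RNA and 0.255 in piRNA-enriched small RNA. The test was tried on simulated data with 200 changed genes per comparison. False calls were 25 of 200 calls at P28, 13 of 192 at P14, 11 of 198 at P18 and 10 of 191 at P10. In testes their share was thus above the threshold of 0.05, most of all at P28. They were 5 of 92 in spermatocytes, and ran from 3 of 89 (P10 piRNA-enriched) to 13 of 145 (P18 without enrichment) in small RNA. Genes changed 4-fold were found in 94% to 100% of cases in testes, 78% in spermatocytes, 0% in round spermatids and 73% to 89% in the small RNA tables, and genes changed 2-fold in 79% to 88%, 9%, 0% and 8% to 43%. In those data 18 of 18 changed gene lists and 1 of 18 unchanged ones had an unadjusted camera p below 0.05. Simulated genes varied independently, so errors on lists of co-regulated genes were not tested.

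Genotypes were compared within each age or cell type (12 comparisons) with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, and a quasi-likelihood F test (glmQLFit and glmQLFTest) in which all libraries of a table share the spread estimate. P values were adjusted by Benjamini-Hochberg over all tested features of a comparison, and an adjusted p below 0.05 counts as changed. In 3 further tests the genotype effect was compared between P18 and P10, between P28 and P18, and between round spermatids and spermatocytes, and 3 tests compared successive ages in heterozygous testes. Values are log2 fold changes of knockout over heterozygous ± standard error, and levels are mean ± SD in CPM (counts per M). Where all libraries of a group had 0 counts, the fold is given as a lower bound with a floor of 3 counts over that group. The labels do not say whether libraries come from separate animals, so p values measure the spread between these samples. No spike-in is recorded in the labels, so all levels are relative to the rest of a library.

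Changes in 16 fixed gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, together with the piRNA loci as all, intergenic and genic sets. The lists are piRNA pathway proteins, meiotic prophase machinery, late pachytene spermatocyte genes, round spermatid genes, elongating spermatid genes, p53 and apoptosis genes, interferon-stimulated genes, sex-chromosome genes silenced in pachytene, integrated stress and unfolded protein response genes, spermatogenic miRNAs, X-linked testis miRNAs, and markers of spermatogonia, Sertoli cells, Leydig cells, peritubular and smooth muscle cells, and macrophages and leukocytes. Counts of members are given after adjustment over all tested features and, where it says so, adjusted over the list alone. Sharing of changed genes was tested with a one-sided Fisher test among features tested in both comparisons. Changes of locus small RNA and locus precursor RNA were compared by Pearson (r) and Spearman (rho) correlation with 10000 permutations of loci, adjusted over a family of 36 tests. Genes and loci are not independent replicates, so these p values describe the sets and not the animals. Class shares of small RNA were compared by an exact permutation test over libraries.

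The text names *Btbd18*; per comparison the 6 largest rises and the 6 largest falls among changed genes of at least 1 CPM whose knockout libraries all lie on the same side of all heterozygous ones, and up to 3 rises and 3 falls with clone-type names; per list up to 3 rising and 3 falling members with the smallest p, or 2 members as plain values where none passed; and per comparison up to 5 falling and 3 rising loci and, in small RNA, 3 rising and 3 falling miRNA genes. For interactions and ages it names up to 5 genes per direction. Of these, the best known are printed. Some genes that the rule names are not reported here. Genes near *Btbd18* on its chromosome are named as a set in the closing part.

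Groups, comparisons, gene lists, the naming rule and all alternatives but 1 were chosen before the data were examined. The alternatives were total counts in place of TMM, RLE scaling, no low-count filter (at least 1 count in all), DESeq2 1.42.0, a test against a 1.5-fold change (glmTreat), the replicate number as a block, only the libraries compared, TMM from miRNA genes alone in small RNA, leaving out each library in turn, camera with an estimated correlation, an adjusted p below 0.01 for overlaps, loci of at least 1 CPM in both tables for correlations, and shares without the most abundant feature. The fit of the piRNA-enriched table without P10 heterozygous replicate 2 and P18 knockout replicate 1 was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.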

Results

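*Btbd18* encodes a nuclear BTB-domain protein and lies on chromosome 2 (84659072 to 84668789). Its RNA was lower in knockout than in heterozygous testes at every age, and knockout libraries kept a small number of counts. At P10 its level was 2.21 ± 0.365 CPM in knockouts against 13.8 ± 0.873 CPM (log2 fold change -2.63 ± 0.19, adjusted p = 2.17e-07), at P14 2.08 ± 0.026 against 18.3 ± 0.16 CPM (-3.13 ± 0.21, adjusted p = 2.90e-08), at P18 3.58 ± 0.84 against 13.7 ± 2.1 CPM (-1.90 ± 0.18, adjusted p = 7.66e-07) and at P28 1.82 ± 0.28 against 8.05 ± 0.78 CPM (-2.14 ± 0.25, adjusted p = 4.61e-07). The fall at P18 did not differ from that at P10 (difference 0.73 ± 0.28, adjusted p = 0.308), nor that at P28 from P18 (-0.24, adjusted p = 0.620). Purified spermatocytes and round spermatids had 0 to 3 counts per library in both genotypes, so the genotype labels of those 12 libraries could not be checked by this gene.

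In small RNA without piRNA enrichment, counts over *Btbd18* were 15 and 17 in heterozygotes against 4 and 8 in knockouts at P10 (-1.66, adjusted p = 1), 26 and 19 against 11 and 19 at P14 (-1.30 ± 0.32, adjusted p = 0.0401), and 27, 34 and 25 against 65, 32 and 33 at P18 (4.76 ± 0.81 against 1.83 ± 0.19 CPM, -1.39 ± 0.22, adjusted p = 1.18e-04, but 0.81 with total counts). In piRNA-enriched small RNA they were 98 and 90 against 47 and 108 at P10, and 75 and 35 against 79 and 45 at P14. At P18 the heterozygous libraries had 30 and 18 counts, knockout replicate 2 had 90, and the library labelled knockout replicate 1 had 395 counts (80.6 CPM against 8.11 CPM in replicate 2 and 6.93 to 9.66 CPM in heterozygotes). *Btbd18* was thus higher in knockouts there (2.38 ± 0.71, adjusted p = 0.0438). Levels of the genotypes overlapped.

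**Figure D1:**
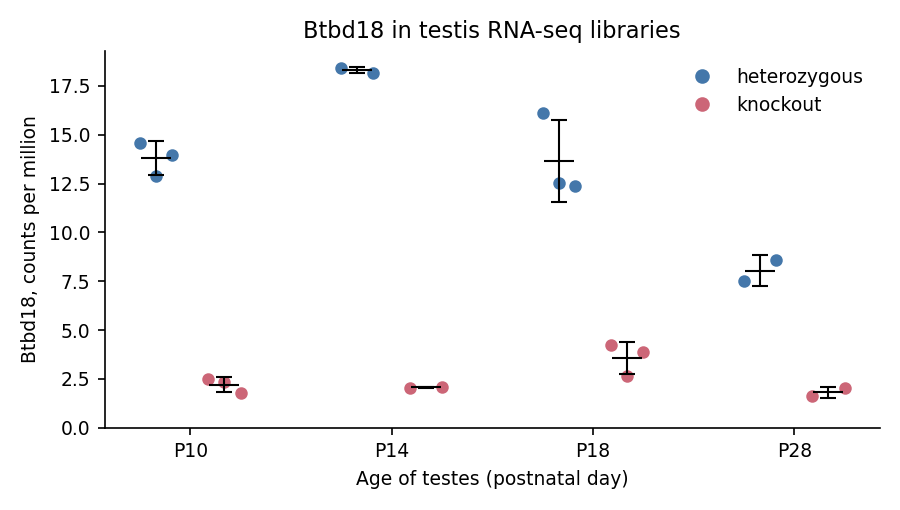
*Btbd18* level (CPM) in testis RNA-seq by age, each point a library, with the mean and SD of each genotype. Knockout libraries (blue heterozygous, red knockout) lie below heterozygous ones at every age, with means of 2.08 against 18.3 CPM at P14.

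Between P10 and P28 the testis of heterozygous animals passed from spermatogonia and early meiosis to elongating spermatids. Its RNA changed accordingly. From P10 to P14, 4675 features rose and 4146 fell. Rises included the axonemal gene *Rsph1* (5.40 ± 0.17, adjusted p = 1.88e-14), the meiotic regulator *Kctd19* (8.34), the spermatocyte chaperone gene *Hspa2* (3.18), the testis lactate dehydrogenase *Ldhc* (9.74) and *Piwil1*, whose product binds pachytene piRNA (4.85). *Amh* (-2.46) and *Sox9* (-1.26) of immature Sertoli cells, the cyclin gene *Ccnd2* (-1.35) and *Jun* (-1.76) fell. Meiotic prophase machinery rose in 24 of 27 members (median 1.86, adjusted p = 1.25e-17, and 0.0668 with an estimated correlation). Late pachytene genes rose in 13 of 18 (4.11, adjusted p = 7.13e-21, and 0.0450) and piRNA pathway genes in 21 of 25 (adjusted p = 1.10e-12, and 0.106). From P14 to P18, 4936 features rose and 4061 fell. There were rises of *Dnah6* (5.41), *Dnah17* (5.10), the sperm surface gene *Adam3* (6.57), the chromatoid body gene *Tdrd6* (4.67) and *Pgk2* (5.06). There were falls of *Crabp1* (-1.44), *Dmrt1* (-1.02) and *Uchl1* (-1.05) of spermatogonia. Round spermatid genes rose in 23 of 28 (2.55, adjusted p = 3.43e-06, and 0.0772 with an estimated correlation) and elongating spermatid genes in 22 of 31 (3.38, adjusted p = 1.79e-06, and 0.165). Spermatogonial markers fell in 14 of 21 (adjusted p = 1.67e-05, and 0.0643). From P18 to P28, 5131 features rose and 5037 fell. *Tnp2* (10.99), *Tnp1* (12.05) and *Prm1* (11.37), which replace histones, rose, as did the Leydig cell gene *Insl3* (2.73). The synaptonemal complex gene *Sycp1* fell (-1.39). All 31 elongating spermatid genes rose (median 7.45, adjusted p = 1.62e-68), whereas 16 of 20 sex-chromosome genes silenced in pachytene fell (-0.91, adjusted p = 1.33e-04, and 0.219 with an estimated correlation). With total counts the share of rises from P14 to P18 was 36.9% in place of 54.9%, and from P18 to P28 31.7% in place of 50.5%.

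Precursor RNA of piRNA loci followed the same course. Of 99 intergenic loci tested, 91 rose and 2 fell from P10 to P14 (median 5.87, adjusted p = 2.72e-48), 98 rose from P14 to P18 (2.95, adjusted p = 1.89e-53), and 59 fell and 5 rose from P18 to P28 (-0.61, adjusted p = 1.24e-04, and 0.575 with an estimated correlation). Rises with the smallest p included 17-qA3.3-26735 (10.79) and 7-qB5-6255 (9.33) by P14 and 5-qF-4633 (3.47) and pi-Ip6k1 (2.38) by P18. Genic loci mostly fell from P10 to P14 (56 of 108, with 14 rises), rose by P18 (72 of 108) and fell by P28 (78 of 108).

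At P10, before pachytene piRNA loci are active, loss of *Btbd18* left testis RNA nearly unchanged. *Btbd18* was the single gene to pass the edgeR test (0 up, 1 down), 1226 features had an unadjusted p below 0.05, and DESeq2 called 13. No piRNA locus passed, and the median of intergenic loci was 0.00. As plain values that did not pass, *Tex11* (0.41 ± 0.08, adjusted p = 0.290), *Smc1b* (0.35) and *Tex15* (0.41) of meiotic chromosomes and *Rnf17* (0.35) of germ granules lay higher, and *Sox9* (-0.33) and *Dhh* (-0.35) of Sertoli cells lower. Meiotic prophase machinery leaned up as a list (0 of 27 passing, 3 adjusted over the list alone, median 0.31, adjusted p = 7.27e-13, and 0.462 with an estimated correlation). So did piRNA pathway genes (1 of 25 adjusted over the list alone, 0.18, adjusted p = 6.08e-06, and 0.699) and late pachytene genes (adjusted p = 0.0332, and 0.881). Sertoli markers leaned down (3 of 20 adjusted over the list alone, -0.10, adjusted p = 8.14e-05, and 0.699).

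At P14, when spermatocytes enter pachytene, the knockout testis lost precursor RNA of intergenic piRNA loci while most other genes kept their level. Among 16334 features 14 rose and 148 fell, and 58 of the falls were piRNA loci. Of 99 intergenic loci 56 fell and none rose (74 adjusted over the list alone, median -1.53, adjusted p = 1.62e-205), 40 of them over 4-fold. Among 108 genic loci 2 fell (median 0.04, adjusted p = 0.410). The loci with the smallest p were 17-qA3.3-26735 (-6.65 ± 0.26, 3.44 ± 2.6 against 330 ± 29 CPM, adjusted p = 1.65e-12), 15-qD1-17920 (-5.31 ± 0.37), 7-qD2-11976 (-6.11 ± 0.40), 14-qA3-19970 (-5.14 ± 0.35) and 6-qF3-8009 (-7.83 ± 0.53). These results rest on 2 libraries per genotype. Without knockout replicate 2 the number of changed features was 47, without knockout replicate 1 it was 347, and with only the libraries compared it was 60.

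Among genes, those of late pachytene cells were reduced at P14. *Ldhc* for sperm glycolysis (-1.16 ± 0.23, adjusted p = 0.0107), the flagellar gene *Spag6* (-1.23, adjusted p = 0.0175) and *Piwil1* (-1.09 ± 0.18, 119 ± 28 against 251 ± 62 CPM, adjusted p = 0.00292) fell. So did *Tdrd6* of the chromatoid body (-1.86 ± 0.28, adjusted p = 6.05e-04). Falls also took in *Tcp11* (-1.77 ± 0.24, adjusted p = 1.74e-04) and *Fabp9* (-0.87, adjusted p = 0.0124) of later germ cells. Others were the perinuclear theca gene *Actl9* (-2.41, adjusted p = 0.0134), the sperm fertilin gene *Adam1b* (-2.29, adjusted p = 0.0202), *Ggnbp1*, a partner of gametogenetin (-2.01, adjusted p = 0.00143), the keratan sulfotransferase gene *Chst1* (-2.06 ± 0.30, adjusted p = 6.05e-04) and *Mroh2a* (-2.05, adjusted p = 0.0102), besides the clones *Gm711* (-1.45) and *1700003M02Rik* (-1.17). The 14 rises included the carbonic anhydrase gene *Car3* (6.06 ± 1.18, 18.1 ± 19 against 0.257 ± 0.36 CPM, adjusted p = 0.0105), the fatty acid binding protein gene *Fabp4* (4.80, adjusted p = 0.00410), the adiponectin gene *Adipoq* (4.77, adjusted p = 0.0268) and the desaturase gene *Scd1* (2.31, adjusted p = 0.0159). With them rose the acute-phase gene *Serpina3n* (4.64, adjusted p = 0.0238) and the bicarbonate transporter gene *Slc4a10* (2.27, adjusted p = 0.0463). Without knockout replicate 2 none of these 6 passed, and *Scd1* was at 0.34. The late pachytene list fell in 6 of 18 members (13 adjusted over the list alone, median -0.82, adjusted p = 2.97e-17, and 0.0467 with an estimated correlation). piRNA pathway genes fell in 2 of 25 (-0.26, adjusted p = 2.18e-07, and 0.402). Round spermatid genes tested lower (0 of 28 passing, 1 adjusted over the list alone, adjusted p = 0.0270, and 0.623 with an estimated correlation) with a median of -0.13 and a mean of 0.04. *Spag16* (-1.07, adjusted p = 0.0610) and *Zpbp2* (-0.97) were its leading members.

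The remaining lists did not pass at P14: elongating spermatid genes (2 of 31 fell, adjusted p = 0.0651), meiotic prophase machinery (0.0612, led by *Tex12* at -0.60), spermatogonial markers (0.0680, with *Id4* at -0.49 and *Zbtb16* at 0.40), Sertoli markers (0.0680, with *Amh* at 0.36), Leydig markers (0.298, with *Star* at 1.12), peritubular markers (0.491), macrophage and leukocyte markers (0.410), p53 and apoptosis genes (0.534), interferon-stimulated genes (0.534), sex-chromosome genes silenced in pachytene (0.410) and stress response genes (0.420).

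**Figure D2:**
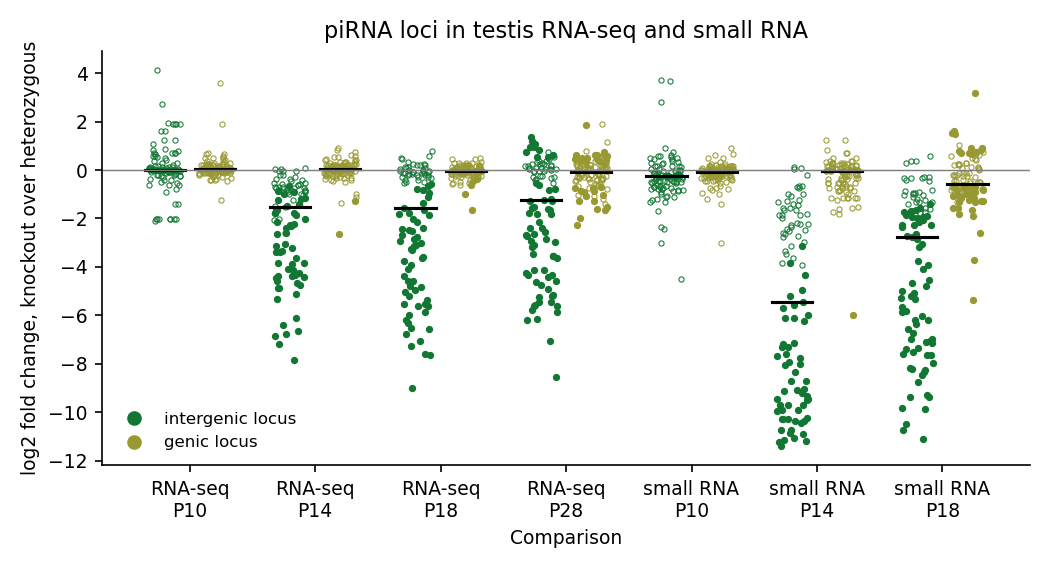
Log2 fold change (knockout over heterozygous) of each tested piRNA locus in testis RNA-seq and in small RNA without piRNA enrichment, by age, with intergenic loci in green, genic loci in olive, filled points for adjusted p below 0.05 and bars for medians. Intergenic loci spread far below 0 from P14 on (RNA-seq medians -1.53, -1.59 and -1.25 at P14, P18 and P28), and genic loci stay around 0 in RNA-seq.

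At P18 the same loci stayed low, and the earliest spermatid transcripts of the heterozygous testis were few or absent in knockouts. In all 58 features rose and 502 fell, and 62 of the falls were loci. With total counts the share of rises was 19.6% in place of 10.4%. Of 99 intergenic loci 57 fell (61 fell and 3 rose adjusted over the list alone, median -1.59, adjusted p = 4.73e-253), 45 of them over 4-fold. Of 108 genic loci 5 fell (adjusted p = 0.898). The leading loci were 15-qD1-17920 (-6.18 ± 0.23, 2.19 ± 0.33 against 158 ± 29 CPM, adjusted p = 6.14e-13), 18-qE1-36451 (-5.20 ± 0.20), 7-qD1-9417 (-7.65 ± 0.26), 6-qD1-2831 (-2.91 ± 0.12) and 10-qB4-6488 (-4.82 ± 0.21). Without knockout replicate 1 the number of changed features was 191, without knockout replicate 2 it was 1228, and with only the libraries compared it was 92. Counts of spermatid genes were few and uneven between the heterozygous libraries, with SDs near the means.

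Genes of the sperm tail, acrosome and spermatid head with no count in any P18 knockout library included *Akap4* of the fibrous sheath (at least 43.0-fold lower, 5.78 ± 6.6 CPM in heterozygotes, adjusted p = 0.00446), *Acrv1* (at least 38.1-fold, adjusted p = 0.00789) and *Spaca4* (at least 14.1-fold) of the acrosome. Others were *Ddi1* (at least 31.3-fold), *Gstt4* (at least 28.9-fold), *Smcp* of the mitochondrial sheath (at least 24.3-fold) and the clone *4921501E09Rik* (at least 30.7-fold). *Odf1* of the outer dense fibres (-4.12, adjusted p = 0.00550), the actin-like *Actl7a* (-3.87, adjusted p = 0.00131), the ubiquitin ligase adaptor *Klhl10* (-3.48 ± 0.63, adjusted p = 0.00315), the meiotic cyclin *Ccna1* (-0.92, adjusted p = 0.0323) and *Pgk2* (-0.74 ± 0.17, adjusted p = 0.0204) fell too. *Chst1*, chosen here after its values were seen, fell again (-3.91, 4.18 against 66.0 CPM, adjusted p = 1.24e-10). Rises were smaller, led by *Ptchd3* of the sperm membrane (1.29 ± 0.16, 638 ± 120 against 261 ± 21 CPM, adjusted p = 3.58e-05), *Schip1* (1.26), the sterol transporter gene *Abcg8* (1.21), the zinc finger pseudogene *Zfa-ps* (1.05), *Ccno* (0.83), *Tmem106c* (0.72) and the Sertoli gene *Clu* (0.27 ± 0.07, adjusted p = 0.0390). Elongating spermatid genes fell in 14 of 31 members (18 adjusted over the list alone, median -0.76 and -0.72 with the genes lacking knockout counts at their bound, adjusted p = 7.54e-11, and 0.0899 with an estimated correlation). Round spermatid genes fell in 6 of 28 (17 fell and 1 rose adjusted over the list alone, -0.52, adjusted p = 8.01e-08, and 0.0803). Late pachytene genes did so in 2 of 18 (6 adjusted over the list alone, -0.37, adjusted p = 9.41e-04, and 0.451).

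Sertoli markers leaned up at P18 (1 of 20 passing, 2 adjusted over the list alone, median 0.13, adjusted p = 0.00595, and 0.451 with an estimated correlation), as did sex-chromosome genes silenced in pachytene (0 of 20, 0.10, adjusted p = 0.0261, and 0.451). piRNA pathway genes did not pass as a list (0 of 25, adjusted p = 0.920, with *Gtsf1* at -0.34 and *Tdrd7* at -0.31). p53 and apoptosis genes (0.0512), spermatogonial markers (0.174), macrophage markers (0.183), meiotic prophase machinery (0.191), interferon-stimulated genes (0.191), stress response genes (0.328), Leydig markers (0.815, with *Star* at -1.36) and peritubular markers (0.920) did not pass.

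By P28 the knockout testis lacked nearly all RNA of elongating spermatids. In total 4203 features rose and 4103 fell. That split depends on scaling: rises were 50.6% of calls with TMM, 71.7% with total counts (7632 up, 3018 down), 35.7% with RLE (2615 up, 4720 down) and 35.1% with DESeq2 (2392 up, 4431 down). Tested against a 1.5-fold change, 172 rose and 2324 fell. The median shift between TMM and total counts was 0.297 log2. All 31 elongating spermatid genes fell (median -10.63 and -8.88 with 4 genes at their bound, adjusted p = 3.77e-74). Among them were *Tnp2* (-11.17 ± 0.17, 0.795 ± 0.086 against 1858 ± 156 CPM, adjusted p = 3.89e-20), *Tnp1* (-14.02 ± 0.27), *Prm1* (-12.42 ± 0.27) and *Prm2* (at least 12917-fold lower), which package the sperm genome, and the spermatid linker histone gene *H1fnt* (at least 2540-fold lower). Genes outside the lists with no knockout count left were the allantoicase gene *Allc* (at least 3484-fold lower), *Actrt2* (at least 3302-fold) and *Actl11* (at least 2275-fold) of the actin-like family and the glutathione transferase gene *Gstt4* (at least 2487-fold).

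Round spermatid genes fell in 25 of 28 members at P28 (median -4.03, adjusted p = 3.15e-14), including the chaperone gene *Hspa1l* (-7.42 ± 0.18, adjusted p = 4.92e-17), the CREM coactivator gene *Fhl5* (-8.95) and the kinase gene *Tssk3* (-8.25). *Tex101*, a germ cell surface gene already active in spermatocytes (1.32, adjusted p = 6.55e-06), and *Taf7l*, of the germ cell TFIID complex (0.61), rose against their list. Of late pachytene genes 11 of 18 fell (14 adjusted over the list alone, -0.58), such as *Pgk2* (-2.05 ± 0.20, adjusted p = 3.96e-08), *Adam3* (-1.05) and *Cdc25c* (-1.25), though not as a list (adjusted p = 0.186). Meiotic prophase machinery divided into 8 rises, among them *Zcwpw1* (0.66), *Tex11* (0.63) and *Hormad2* (0.78), and 4 falls, among them the cohesin gene *Rec8* (-2.41), *Syce2* (-0.79) and *Syce3* (-0.99; list adjusted p = 0.186). Among piRNA pathway genes *Mov10l1* (0.41) and *Fkbp6* (0.33) rose and *Gtsf1* (-1.39, adjusted p = 5.85e-09), *Tdrd7* (-0.85) and the helicase gene *Ddx25* (-0.79) fell (2 up, 5 down of 25, list adjusted p = 0.601).

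At P28 Sertoli markers rose in 15 of 20 members (16 adjusted over the list alone, median 0.55, adjusted p = 0.00392, and 0.391 with an estimated correlation), with *Clu* (0.57), *Aard* (0.75) and *Cldn11* (0.64). Spermatogonial markers rose in 11 of 21 (0.49, adjusted p = 0.0318, 0.0710 with total counts and 0.391 with an estimated correlation), with *Ccnd2* (0.86), *Uchl1* (0.62) and *Dmrt1* (0.55). *Gfra1* (-0.76) and *Lhx1* (-3.24), of stem cells responding to GDNF, fell against that list. Interferon-stimulated genes rose in 11 of 17 (14 adjusted over the list alone, 0.98, adjusted p = 0.0142, 0.0549 with total counts and 0.391 with an estimated correlation), with *Oasl2* (1.13) and *Ifih1* (1.04). Among the largest rises were the antigen presentation gene *H2-Aa* (3.27 ± 0.52, adjusted p = 3.18e-05) and the chemokine genes *Ccl8* (2.98) and *Cxcl14* (3.06). Beside them rose the matrix gene *Hapln1* (3.11 ± 0.33, adjusted p = 1.14e-07), *Cmya5* (3.13), *Cyp2c55* (3.43) and the clones *2410141K09Rik* (4.98) and *Gm11545* (4.72). p53 and apoptosis genes rose in 12 of 19 (0.53, adjusted p = 0.0213, and 0.254 with an estimated correlation), with *Btg2* (1.11), *Apaf1* (0.65) and *Sesn1* (0.53). The same held for sex-chromosome genes silenced in pachytene in 12 of 20 (0.47, adjusted p = 0.0213, and 0.391), with *Hprt* (0.84), *Ddx3x* (0.76) and *Atrx* (0.90).

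Other lists held changed members at P28 without passing as a whole. Leydig markers (3 of 12 up, median 0.46, adjusted p = 0.161) were led by *Hsd17b3* (1.10) and *Hsd3b1* (0.82). Macrophage and leukocyte markers (9 up and 1 down of 14, 0.82, adjusted p = 0.368) were led by *C1qa* (1.04) and *Ptprc* (1.38), with *Aif1*, also transcribed in spermatids, down (-5.69). Peritubular markers had a median of 0.20, a mean of -0.26 and a test towards lower (adjusted p = 0.774): *Mylk* (0.47) rose and the smooth muscle actin gene *Actg2* fell (-4.17). Stress response genes divided into 7 rises, with *Atf4* (0.56) and *Atf3* (at least 5.12-fold higher), and 4 falls, with *Herpud1* (-1.24), *Asns* (-1.47) and *Chac1* (-2.82; list adjusted p = 0.508).

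Among intergenic piRNA loci at P28, 55 of 99 fell and 10 rose (median -1.25, and -0.95 with total counts, adjusted p = 4.35e-09, and 0.391 with an estimated correlation), led by 6-qD1-2831 (-3.53 ± 0.15, adjusted p = 1.06e-13), 15-qD1-17920 (-5.78), 18-qE1-36451 (-4.64), 7-qD1-9417 (-5.58) and 18-qE1-1295 (-8.55 ± 0.35). Rising loci were 7-qD2-40 (0.73 ± 0.10, adjusted p = 4.51e-06), 10-qA3-2592 (1.36) and 9-qA1-178 (0.95). With TMM 16 genic loci rose and 15 fell of 108 (median -0.07, but 0.22 with total counts, adjusted p = 0.411).

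**Figure D3:**
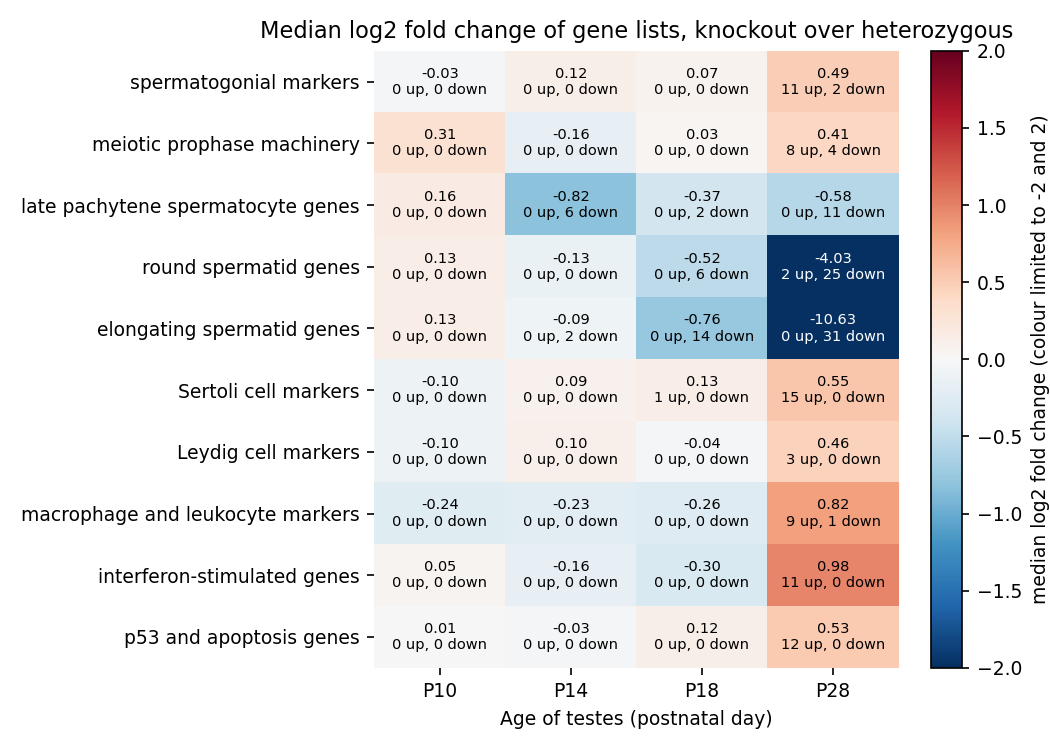
Median log2 fold change (knockout over heterozygous) of 10 gene lists in testes of each age, as colour and number, with the members that rose and fell. The fall of elongating spermatid genes grows from -0.76 at P18 to -10.63 at P28, and Sertoli and spermatogonial markers stand at 0.55 and 0.49 at P28.

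A common set of loci was low at all 3 later ages. Precursor RNA of 47 loci, 46 of them intergenic, fell at P14, P18 and P28, out of 84 that fell at any. The falls shared between P14 and P18 were 68 against 4.55 by chance (Fisher p = 2.42e-63), 50 of them loci, and 18 were other genes (2.46 by chance, p = 3.09e-11). No rise was shared. P18 and P28 shared 449 falls (126 by chance, Fisher p = 3.19e-212) and 42 rises (14.9 by chance, p = 1.21e-13). P14 and P28 shared 115 falls (37.2 by chance, Fisher p = 2.96e-41).

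Between P10 and P18 the genotype effect differed for 25 features (7 up, 18 down), of which 7 were loci: 6-qD1-2831 (-2.97 ± 0.23, adjusted p = 8.71e-07), 9-qC-10667 (-3.99), 10-qB4-6488 (-4.65), 15-qE1-1119 (-3.49) and 17-qE1.1-7037 (-4.10) had the smallest p. Beside them stood *Chst1* (-3.48 ± 0.40, adjusted p = 1.31e-04), the zinc finger gene *Zfp820* (-2.76), the deubiquitinase gene *Stambp* (-1.33) and the mitotic kinase gene *Plk1* (-0.85). Upward moved *Sox9* (0.70, adjusted p = 0.0495) and *Prelid1* (0.66). Intergenic loci shifted down as a set (adjusted p = 2.04e-10, and 0.444 with an estimated correlation). Between P18 and P28 it differed for 3875 features (1798 up, 2077 down), with rises in 77.1% of calls with total counts and 23.0% with DESeq2 in place of 46.4%. Elongating spermatid genes moved down in 24 of 31 (median -6.77, adjusted p = 2.83e-21). Interferon-stimulated genes moved up in 10 of 17 (adjusted p = 2.24e-04, and 0.300 with an estimated correlation) and Sertoli markers up in 7 of 20 (adjusted p = 0.00644, and 0.532). *Clpb* (-3.05 ± 0.11, adjusted p = 3.77e-13), *Stard10* (-4.07) and *Dgat2* (-2.87) led the falls. *Hapln1* (3.89 ± 0.41, adjusted p = 5.06e-07), *Cd74* (4.56) and *H2-Eb1* (4.96) led the rises. Of 99 intergenic loci 14 moved up and 2 down (adjusted p = 0.00681, and 0.809 with an estimated correlation).

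In purified spermatocytes of adults, the loss centred again on intergenic piRNA loci. Among 4618 features 93 rose and 131 fell, or 50.8% rises with DESeq2 in place of 41.5%. Of 78 intergenic loci 35 fell and 1 rose (41 fell and 2 rose adjusted over the list alone, median -1.19, adjusted p = 9.53e-28, and 0.0305 with an estimated correlation). Among 33 genic loci 2 fell. The falls with the smallest p were at 6-qF3-8009 (-5.46 ± 0.46, 9.83 ± 4.1 against 436 ± 150 CPM, adjusted p = 1.74e-06), 12-qE-23911 (-7.86), 7-qD1-19431 (-5.65), 14-qA3-19970 (-4.53) and 6-qF3-28913 (at least 47.9-fold lower), and 9-qC-10667 rose (1.27, adjusted p = 0.0482). Of 42 core loci tested 31 fell here, while 9-qC-10667, itself a core locus, rose. Falls shared with P18 testes were 41 against 6.42 by chance (Fisher p = 1.45e-23), mostly loci (34, against 18.7 by chance, p = 1.50e-10). Of other genes 7 were shared (3.48 by chance, Fisher p = 0.0578), and 4 at an adjusted p below 0.01 (0.427 by chance, Fisher p = 7.88e-04). Without knockout replicate 2 the count of changed features was 24, and without heterozygous replicate 1 it was 427.

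Genes that fell in spermatocytes included the long noncoding RNA gene *Gldnos* (-7.21 ± 0.41, 11.2 ± 5.3 against 1706 ± 414 CPM, adjusted p = 2.86e-08), antisense to gliomedin, the mucin gene *Muc20* (-7.48), the fatty acid isomerase gene *Eci3* (-7.57) and *Tmem82* (-7.05). To these add the folate enzyme gene *Aldh1l1* (at least 64.9-fold lower), *Mroh5* (at least 52.5-fold lower) and the spermatid kinase gene *Tssk1* (-3.97 ± 0.71, adjusted p = 0.00308). Those that rose included the EGFR inhibitor gene *Errfi1* (3.63 ± 0.41, 816 ± 389 against 65.3 ± 18 CPM, adjusted p = 4.68e-05), the potassium channel gene *Kcnk12* (3.73, adjusted p = 0.00436), *Kndc1* (3.68), *Tmem102* (3.06), the metalloprotease gene *Mmp25* (2.76) and *Kptn* (2.69). Levels in this table may partly stand for an overlapping gene, as the closing part sets out. piRNA pathway genes leaned down without a member passing (0 of 20, median -0.68, adjusted p = 0.00748, and 0.667 with an estimated correlation), with *Mov10l1* (-1.59) and *Rnf17* (-1.19) leading. Meiotic prophase machinery (0 of 10, adjusted p = 0.0694, with *Sycp1* at -1.56), elongating spermatid genes (1 of 13 down, 0.274), late pachytene genes (0 of 15, 0.309), round spermatid genes (0 of 13, 0.584) and stress response genes (0 of 6, 0.386) did not pass.

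Knockout cells purified as round spermatids held little RNA of spermatids. Among 6703 features 1317 rose and 1236 fell, with rises at 51.6% of calls, but 31.1% with DESeq2 and 32.3% with RLE. Median shifts were 0.340 log2 (total counts) and -0.923 log2 (RLE) against TMM. Elongating spermatid genes fell in 23 of 29 (27 adjusted over the list alone, median -5.37 and -5.28 with genes at their bound, adjusted p = 3.98e-09, and 0.266 with an estimated correlation), with *Actl7b* (-6.96), *Smcp* (-6.75) and *Odf1* (-7.17). Round spermatid genes fell in 18 of 26 (-4.33, adjusted p = 6.66e-05, and 0.266), with *Acrv1* (-7.29), the sperm calcium channel gene *Catsper4* (-6.84) and *Spaca7* (-6.41). Late pachytene genes fell in 5 of 15 (-2.84, adjusted p = 0.00690, and 0.867), with *Ovol1* (-4.20), *Clgn* (-2.77) and *Adam2* (-4.49). Spermatogonial markers rose in 9 of 10 (8.57, and 6.08 with genes at their bound, adjusted p = 1.41e-05, and 0.266), with *Uchl1* (8.25, adjusted p = 0.00454), *Dmrt1* (8.07) and *Zbtb16* (at least 71.5-fold higher), while the GDNF receptor gene *Gfra1* fell (-2.73). Sex-chromosome genes rose in 3 of 4 (adjusted p = 0.0151, and 0.266), with *Atrx* (3.20) and *Usp9x* (1.90). The knockout libraries are shallow (from 0.194 M counts) and unlike each other, and the test found 0% of simulated changes. Without any 1 of the 3 heterozygous libraries the count was 0, and without knockout replicate 2 it was 5254.

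Among the largest changes by fitted fold in this fraction were rises from no heterozygous count of the X-linked genes *Pdha1* (at least 316-fold higher), *Map3k15* (at least 259-fold) and *Tmem255a* (at least 181-fold), and of *Tnk1* (at least 250-fold), *Dlx1as* (at least 168-fold) and *Mfsd4* (at least 159-fold). *Pdha1* and *Map3k15* overlap on the chromosome, so each level may hold reads of the other. Other levels in this fraction, made with the same stranded kit as spermatocytes, may likewise hold reads of an overlapping gene. Single markers of somatic cells rose, *Ctsl* (at least 56.3-fold) of Sertoli cells, *Star* (4.00) of Leydig cells and *Tagln* (2.06) of peritubular cells, as did the stress gene *Sel1l* (2.71). As lists, Leydig markers (1 up and 1 down of 3 tested, median -1.37, adjusted p = 0.837), peritubular markers (1 up of 3, 0.06, but -0.85 with DESeq2, adjusted p = 0.837) and stress response genes (2 up of 11, 0.61, but -0.33 with DESeq2, adjusted p = 0.341) did not pass. Genes with no count left in knockouts were *Utp23* (at least 235-fold lower), *Spata21* (at least 216-fold), *Asb17os* (at least 155-fold), *Cdc20b* (at least 120-fold), *Nrn1* (at least 111-fold), *Serpinb9b* (at least 91.2-fold) and the interferon-inducible *Xaf1* (at least 12.4-fold). Among piRNA pathway genes *Tdrd1* (3.98), *Mov10l1* (3.02) and *Piwil2* (4.58) rose, and *Tdrd6* (-3.45), *Ddx25* (-3.45) and *Mael* (-1.85) fell (6 up, 4 down of 17, median -0.13, and 0.37 with total counts, adjusted p = 0.732). Of 45 intergenic loci 30 fell and 7 rose (median -4.43 and -4.20 with loci at their bound, adjusted p = 8.23e-05, and 0.266 with an estimated correlation). Lower were pi-Ip6k1 (-3.16 ± 0.43, adjusted p = 0.00567), 3-qA2-617 (-6.16), 14-qA3-2286 (-7.34), 8-qA4-155 (-7.04) and 14-qA3-3095 (at least 79.3-fold lower). Higher were 10-qC1-12816 (3.42), 10-qB4-6488 (6.21) and 7-qD2-40 (at least 86.7-fold higher). The first 2 of these belong to the core loci that were low in testes at P14, P18 and P28, and of 21 core loci tested in this fraction 14 fell and 4 rose. Falls shared with P28 testes were 857 against 460 by chance (Fisher p = 5.23e-151) and rises 730 against 280 (p = 6.09e-219).

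Set against spermatocytes, the genotype effect in round spermatids differed for 1598 features (739 up, 859 down), 45 of them loci. Rises were 46.2% of calls, 68.7% with total counts and 31.7% with DESeq2, at a median shift of 0.896 log2 for total counts. *Rad9a* (8.64), *Ncl* (7.40), *Mettl5* (6.18), *Dazl* (7.89) and *Uchl1* (9.46) moved up. The phosphatase genes *Alpi* (-9.57) and *Alppl2* (-7.73), *Gpr179* (-7.30), *Actl7b* (-6.85) and *Tnp2* (-6.66) moved down. Spermatogonial markers moved up in 6 of 10 (adjusted p = 4.65e-04, and 0.390 with an estimated correlation) and elongating spermatid genes down in 11 of 29 (adjusted p = 7.70e-04, and 0.684). Falls shared by both fractions were 72 (16.7 by chance, Fisher p = 3.01e-34) and rises 3 (6.999 by chance, p = 0.979).

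Small RNA of the loci followed their precursors. At P10 loci held 2.03 ± 0.158% of small RNA counts in knockouts and 1.61 ± 0.114% in heterozygotes. No feature passed (edgeR), 319 had an unadjusted p below 0.05 and DESeq2 called 0, but 46 passed with only the libraries compared. The median of intergenic loci was -0.27, and 0.08 with total counts (adjusted p = 0.0170, and 0.679 with an estimated correlation). By P14 loci held 49.7 ± 37.7% of the counts in heterozygotes but 5.08 ± 1.92% in knockouts. By P18 it was 58.5 ± 3.92% (54.1% to 61.6%) against 15.9 ± 9.47% (10.0% to 26.8%; exact permutation p = 0.1, the smallest possible with 3 against 3). At P18 miRNA genes held 23.2 ± 4.17% in knockouts against 11.5 ± 1.25% (exact permutation p = 0.1), and snoRNA genes held 42.5 ± 17.01% against 24.8 ± 2.42% (exact permutation p = 0.400). With so large a class missing, scaling sets the level of all the rest, and directions below are relative to TMM unless stated.

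**Figure D4:**
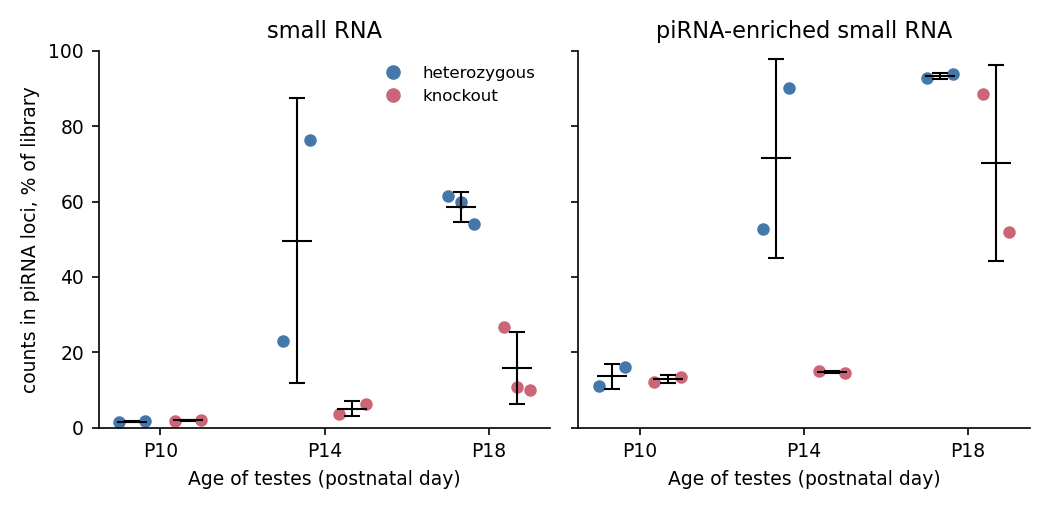
Share of counts (%) held by piRNA loci in each small RNA library, without (left) and with (right) piRNA enrichment, by age and genotype, with mean and SD. At P18 loci hold 54.1% to 61.6% in heterozygous and 10.0% to 26.8% in knockout libraries without enrichment. The piRNA-enriched P18 knockout libraries lie apart, at 88.5% and 51.8%.

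At P14 small RNA of 143 features rose and 96 fell, 56 of them loci. Rises were 59.8% of calls, 94.4% with total counts (1215 up, 72 down, shift 1.07 log2) and 13.0% with TMM from miRNA genes (7 up, 47 down). Of 99 intergenic loci 55 fell and none rose (83 adjusted over the list alone, median -5.44, and -3.58 with total counts, adjusted p = 3.75e-79, and 0.0363 with an estimated correlation). Of 104 genic loci 1 fell. The strongest falls by p were 9-qC-31469 (-10.75 ± 1.16, 28.0 ± 8.4 against 48172 ± 55126 CPM, adjusted p = 6.87e-05), 7-qD2-24830 (-10.85), 12-qE-7089 (-10.25), 10-qC1-117 (-6.12) and pi-1700016M24Rik (-6.00). *Chst1* fell as in RNA-seq (-7.29 ± 0.79, adjusted p = 7.03e-05). *Elfn2* (-3.68) and *Ptchd3* (-3.90) fell too. Spermatogenic miRNAs fell in 4 of 9 (5 adjusted over the list alone, median -1.93, and -0.46 with total counts, adjusted p = 4.22e-06, and 0.0354 with an estimated correlation), with *Mir449a* (-4.22 ± 0.65, 21.3 ± 3.1 against 398 ± 433 CPM, adjusted p = 9.99e-04) and *Mir449c* (-3.33) of the multiciliated and spermatocyte cluster and *Mir184* (-2.18). *Mir375* fell too (-3.16). X-linked testis miRNAs did not pass (0 of 16, -0.32, and 0.58 with total counts, adjusted p = 0.135). Small RNA over several genes rose: *Tdrd6* (2.12 ± 0.36, adjusted p = 0.00255), the piRNA biogenesis factor gene *Exd1* (1.71), the manchette gene *Rimbp3* (3.14, adjusted p = 7.88e-04), *Clgn* (1.74). The same held for the testis poly(A) polymerase gene *Papolb* (1.72), *Prss23* (2.98), *Slc35g3* (2.95), *Perm1* (2.92), *Zfp536* (2.90) and *Hspa12b* (2.78). With only the libraries compared no feature passed. Without knockout replicate 2 the count of changed features was 67, and without heterozygous replicates 1 and 2 in turn it was 820 and 583. In the heterozygous libraries loci held 23.0% and 76.4% of counts (95% intervals 22.96 to 23.03 and 76.33 to 76.38, for counting error alone).

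At P18 small RNA of 2092 features rose and 1838 fell, 98 of them loci. Rises were 53.2% of calls, 99.2% with total counts (8391 up, 68 down, shift 2.19 log2), 98.0% with TMM from miRNA genes (5307 up, 108 down, shift 1.18 log2) and 63.2% without the low-count filter, so whether the bulk rose or fell is not settled. Intergenic loci fell in 68 of 99 (74 adjusted over the list alone, median -2.78, -0.38 with total counts and -1.58 with TMM from miRNA genes, adjusted p = 1.56e-28, and 0.147 with an estimated correlation). Genic loci had 30 falls and 12 rises of 104 (median -0.56, but 1.58 with total counts and 0.61 with TMM from miRNA genes, adjusted p = 0.0105, and 0.147). The losses with the smallest p were at 7-qD1-16444 (-10.72 ± 1.02, adjusted p = 8.31e-07), 9-qC-31469 (-9.37 ± 0.90, 166 ± 58 against 109507 ± 12176 CPM), 7-qD2-24830 (-9.36), 12-qE-7089 (-8.33) and pi-1700016M24Rik (-5.38). By contrast pi-Exoc8 (3.16), pi-Tktl2 (1.48) and pi-Hjurp (1.53) rose. Of the 47 core loci 46 fell here and 45 in P14 small RNA.

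Genes with small RNA far higher in P18 knockouts were the kinase gene *Hipk2* (4.62 ± 0.38, 11.2 ± 0.98 against 0.444 ± 0.26 CPM, adjusted p = 3.11e-07), the calcium channel gene *Ryr3* (4.09), *Zfp536* (4.07), *Rimbp3* (3.91), *Dyrk1b* (3.66), *Farp2* (3.56). Others were *Tdrd6* (3.55 ± 0.29, 109 ± 7.8 against 9.32 ± 1.2 CPM, adjusted p = 3.29e-07), *Exd1* (2.42), the acrosin gene *Acr* (2.71), *Papolb* (2.38), the meiotic cohesin gene *Stag3* (1.61) and *Star* (1.48). Lower were *Chst1* (-5.40, adjusted p = 2.16e-07), the protocadherin gene *Pcdhgc3* (-4.96), the polarity gene *Dlg5* (-4.95), *Prok2* (-3.99), the chromatin gene *Hmga1* (-3.92) and *Toporsos* (-3.91). Spermatogenic miRNAs were lower in 9 of 9 (median -2.02 with TMM, -0.84 with TMM from miRNA genes but 0.26 with total counts, adjusted p = 2.79e-06, and 0.0413 with an estimated correlation), with *Mir449a* (-3.85), *Mir449c* (-3.30) and *Mir328* (-3.68 ± 0.29, adjusted p = 2.33e-07), the last outside that list. X-linked testis miRNAs were lower in 12 of 16 (-1.15, but 1.03 with total counts and 0.02 with TMM from miRNA genes, adjusted p = 4.45e-05, and 0.147). Small RNA over piRNA pathway genes divided (5 up, 6 down of 24, median -0.27, but 1.93 with total counts and 0.90 with TMM from miRNA genes, adjusted p = 0.855). P14 and P18 shared 87 falls (16.96 by chance) and 141 rises (28.8 by chance, Fisher p = 8.13e-97).

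In piRNA-enriched libraries loci held 12.9 ± 1.07% of counts in knockouts and 13.6 ± 3.405% in heterozygotes at P10, 14.8 ± 0.243% against 71.5 ± 26.4% at P14, and 70.2 ± 25.9% against 93.4 ± 0.765% at P18 (exact permutation p = 0.333 is the smallest possible with 2 against 2). At P10 no feature passed (edgeR), 236 had an unadjusted p below 0.05, DESeq2 called 7, and 1 passed with only the libraries compared. Of 98 intergenic loci 79 lay below 0 (median -1.14, adjusted p = 5.51e-14, and 0.679 with an estimated correlation), which rests on heterozygous replicate 2: without it 40 of 99 lay below 0 (median 0.07). Intergenic loci held 5.29% of its counts, against 1.98% in heterozygous replicate 1 and 2.14% and 2.25% in knockouts. All loci held 16.0% of counts (95% interval 16.00 to 16.08) in heterozygous replicate 2 and 11.2% (11.18 to 11.26) in replicate 1, counting error alone. The spermatogonial RNA-binding gene *Nanos2* was at -2.81 (adjusted p = 0.259). At P14, 0 features rose and 41 fell, 30 of them loci, with 29 of 98 intergenic loci passing (92 adjusted over the list alone, median -5.97, and -3.25 with total counts, adjusted p = 2.85e-103, and 0.0298 with an estimated correlation). 10-qC1-117 (-5.20 ± 0.66, adjusted p = 0.00378), pi-1700016M24Rik (-7.62), 9-qF4-150 (-5.22), 7-qF3-246 (-6.03) and 14-qC1-1261 (-9.40) came first. *Chst1* (-5.47 ± 0.81, adjusted p = 0.00725), *Dlg5* (-4.57), *Elfn2* (-3.93), *Hmga1* (-3.83), *Gpr35* (-3.66), *Pla2g2d* (-3.43) and *Nanos2* (-2.47, adjusted p = 0.0266) fell as well. Falls shared with the small RNA libraries lacking enrichment were 35 (0.366 by chance, Fisher p = 1.86e-69). The labels do not say whether both preparations came from the same testes, so the lists may not be independent. Spermatogenic miRNAs were lower (0 of 8 passing, 4 adjusted over the list alone, -0.94, but 0.78 with total counts, adjusted p = 7.68e-04, and 0.0970 with an estimated correlation). With only the libraries compared, as without knockout replicate 1, the count at P14 was 0, and without heterozygous replicate 1 it was 1115.

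At P18 the piRNA-enriched knockout libraries did not resemble each other: loci held 88.5% of counts (95% interval 88.49 to 88.52, counting error alone) in the library labelled knockout replicate 1 and 51.8% (51.81 to 51.88) in replicate 2. Accordingly 1 of 98 intergenic loci fell, 10-qC1-875 (-3.52 ± 1.08, adjusted p = 0.0492), although 90 lay below 0 (median -1.19, but 0.42 with total counts, adjusted p = 4.99e-12, and 0.448 with an estimated correlation). By contrast pi-Hjurp (1.67) and pi-Tacc1 (1.25) rose among genic loci. In all 1131 features rose and 135 fell, rises being 89.3% of calls and 99.9% with total counts (4591 up, 3 down, shift 2.004 log2). Among them *Tdrd6* (3.41 ± 0.46, adjusted p = 7.26e-04), *Exd1* (1.90), *Rimbp3* (3.93), *Star* (1.94), the ciliary regulator gene *Rfx2* (2.30), *Arntl2* (5.67), *Fras1* (3.84) and *Etv4* (at least 6.77-fold higher) rose. *Cenpk* (-3.36, adjusted p = 6.49e-04), *Hmga1* (-3.15), *Srd5a1* (-2.47), *Mir184* (-1.69) and *Mir29a* (-1.02) were lower. Rises shared with P18 small RNA lacking enrichment were 1009 (229 by chance) and falls 68 (20.5 by chance, Fisher p = 5.19e-23). Here too both preparations may come from the same testes. Spermatogenic miRNAs (1 of 8, -0.92, but 0.89 with total counts, adjusted p = 0.0109, and 0.448 with an estimated correlation) and X-linked miRNAs (0 of 16, -0.51, but 1.46 with total counts, adjusted p = 3.93e-04, and 0.448) tested lower. Without heterozygous replicate 1 the count was 3, and without the library labelled knockout replicate 1 it was 2277.

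Locus by locus, loss of small RNA tracked loss of precursor. At P14 the log2 fold changes correlated with r = 0.863 (rho = 0.795) over 201 loci, r = 0.777 over 99 intergenic and r = 0.491 over genic loci. At P18 the values were r = 0.921 (rho = 0.605), 0.928 and 0.289. For all loci and for intergenic loci the permutation p of r and rho was 0.0001, the smallest that 10000 permutations can give (0.0002 adjusted over 36 tests). Over genic loci r passed (adjusted permutation p = 0.0002 at P14 and 0.0144 at P18), and rho did not (0.095 with adjusted permutation p = 0.553, and 0.024 with 0.863). Precursor and small RNA both fell at 45 loci at P14 and at 53 at P18. Precursor alone was called lower at 13 and 9 loci, and small RNA alone at 11 and 45. Of the 45 at P18, 29 were genic loci called with TMM. The median small RNA change of all genic loci at P18 was a rise with total counts and with TMM from miRNA genes, so these calls may depend on scaling. The correlation with piRNA-enriched small RNA was r = 0.870 at P14 and 0.730 at P18, and at P10, where no precursor passed, r = 0.0619 with small RNA (adjusted permutation p = 0.409). Among loci of at least 1 CPM in both at P10 it was 0.215 (adjusted permutation p = 0.0309), with a rho of 0.102 that did not pass. Over all 102 genic loci tested at P10 r was 0.260 with small RNA (adjusted permutation p = 0.0236), but 0.192 among those of at least 1 CPM (adjusted permutation p = 0.0888). With piRNA-enriched small RNA at P10 r was -0.0143 over all loci and -0.573 over genic loci (adjusted permutation p = 0.00170), but 0.0630 among genic loci of at least 1 CPM (adjusted permutation p = 0.571).

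**Figure D5:**
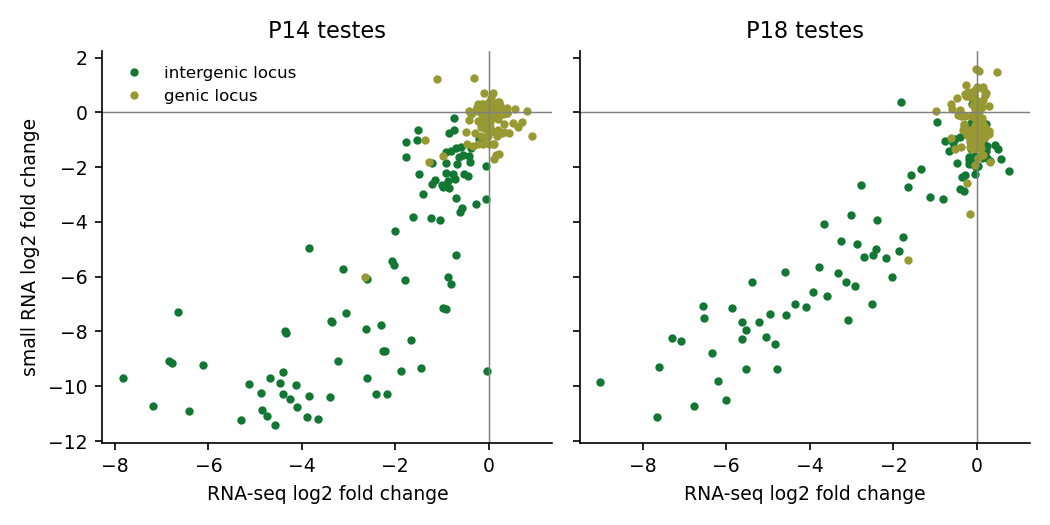
Log2 fold change (knockout over heterozygous) of small RNA against that of precursor RNA for each piRNA locus at P14 (left) and P18 (right), with intergenic loci in green and genic loci in olive. Falls of precursor and of small RNA go together (r = 0.863 at P14 and 0.921 at P18). Still, 13 and 9 loci were called lower in precursor alone, and 11 and 45 in small RNA alone. Of these 45, 29 are genic loci, whose calls may depend on TMM scaling.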

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

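All 3 tests on the P18 piRNA-enriched library, the overlap test on purified cells, the comparison of marker lists, the sorting of splits by the grouping they kept, the thinning to the shallowest library and the scaling check of elongating spermatid genes at P28 were chosen only after the result was seen, and the other tests before.

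The effect of the knockout was set against itself between ages and between cell types, and each difference that passed stands here. Round spermatids differed from spermatocytes at 1598 features and 45 piRNA loci, P18 testes from P10 testes at 25 features and 7 loci, and P28 from P18 testes at 3875 features and 24 loci. Regrouping the libraries at random gave as many features as the real grouping in 6 of 100 splits for round spermatids against spermatocytes, the real split included, with 2309 as the highest other. The other 5 all kept the real grouping of the round spermatid libraries, so they hold that genotype effect and leave chance undecided. All 75 splits that regrouped both fractions gave 0. For P18 against P10 it did so in 1 of 100 splits, the real one, with 24 as the highest other. Among the simple comparisons with 3 libraries a side only 10 splits exist, too few for a p under 0.05: the real split gave 1 at P10 (highest other 6, with 4 of 10 splits as large), 560 at P18 (highest other 74), 224 in spermatocytes (highest other 0), 2553 in round spermatids (highest other 0) and 3930 in P18 small RNA (highest other 1).

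The library labelled knockout replicate 1 of P18 piRNA-enriched small RNA kept locus small RNA that other knockout libraries lost: over 24 loci at least 10-fold lower in replicate 2, it stood at a median of 78.0% of the heterozygous level, against 4.64% in replicate 2. Heterozygous material mixed in might explain these loci, but the fraction it would need ran from 41.5% to 96.5% between the 10th and 90th percentiles of loci, a ratio of 2.32, which leaves it open. A wrong genotype label is likewise open: over 1215 other features the library lay at 0.369 of the way from heterozygous to knockout (95% interval 0.363 to 0.377, over features). That position rests on shares of total counts, which the locus share of each library moves, so it is not independent of the loci. Neither mixing nor a wrong label accounts for the *Btbd18* level of this library, 26.4 counts per M of total counts, above 9.63 in replicate 2 and at most 1.82 in P18 heterozygotes. Scaling was tested on the same 24 loci. Their median share of counts in this library was 18.4 times that in replicate 2, and the TMM factor ratio was 0.275. These loci were chosen for being low in replicate 2, so the ratio cannot exclude scaling. All loci together held 88.5% of counts in this library and 51.8% in replicate 2, shares that use no TMM factor. No biological explanation was tested.

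Purified spermatocytes ranked genes unlike testes, and so did purified round spermatids. Spermatocyte libraries of both genotypes had Spearman correlations of 0.467 to 0.634 with P18 heterozygous testes. Round spermatid libraries had 0.278 to 0.607 with P28 heterozygous testes. The tests on overlapping genes below used spermatocyte levels. Whether reads were counted throughout on the strand opposite to the transcript is open. Over 2794 overlapping genes levels followed a gene's own testis level more than that of its partner (Spearman 0.490 against 0.261, difference -0.230, 95% bootstrap interval -0.283 to -0.178). Partners were found by position without regard to strand, so this test cannot decide the question. Reads of an overlapping gene may account for part of the unlike ranking: of 512 features more than 10-fold above their testis level 44.9% overlap a gene of at least 50 CPM, against 11.3% of the rest (Fisher p = 1.26e-67). Counting noise from low depth alone is argued against, since testis libraries thinned to the deepest spermatocyte library kept a Spearman correlation of at least 0.9747 with full ones, and of at least 0.948 when thinned to the shallowest purified library. Thinning adds no noise from library preparation, which was not tested. Spermatocyte replicates of the same genotype had Spearman correlations of 0.706 to 0.885 with each other. A biological difference in cell makeup stays open, as the ribosomal protein gene share was lower than in testes by 2.36 to 3.49 times between single libraries.

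Among the 4103 lower genes of P28 knockout testes are those the testis gains after P18. Over 1556 genes that gained more than 4-fold from P18 to P28 in heterozygotes (median 4.61), knockouts gained a median of 0.20 log2, and 96.1% were lower in knockouts, which is consistent with a missing late stage. Fewer spermatids as the only change is open. Medians of other cell types moved apart, from 0.20 (peritubular) to 0.82 (macrophage and leukocyte, permutation p over genes = 0.0005). Genes are not replicates, and the lists hold genes that spermatids also transcribe, such as *Aif1*, so this test cannot decide. TMM scaling as the cause is open for the lower genes as a whole. Of these, 73.6% stayed lower with total counts and none turned higher. All 4103 stayed lower with RLE, but RLE moved fold changes further down than TMM, so that cannot count against TMM. TMM scaling is argued against for elongating spermatid genes, a list fixed beforehand. Of these, 96.8% (30 of 31) stayed lower with total counts. The bound of 90% was set after a stricter one on every member had been missed by *Fabp9* at -0.27.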

How the results depend on the processing

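Every setting below was chosen before the data were seen, except the fit of piRNA-enriched small RNA without P10 heterozygous replicate 2 and P18 knockout replicate 1, chosen after the result was seen. Groups hold 2 or 3 libraries, and leaving out 1 of 2 assumes that the lone library varies like the other groups. In round spermatids, with a biological coefficient of variation of 0.703, the test found 0% of simulated 4-fold changes. Of the named genes and loci that passed, RLE scaling kept 268 of 272, total counts 310 of 331, DESeq2 305 of 331, no low-count filter 322 of 331, the test against 1.5-fold 212 of 272, the replicate block 253 of 272, only the libraries compared 139 of 194, fits without 1 library 1442 of 1794 (351 lost, 1 reversed) and TMM from miRNA genes 65 of 82. Among gene list calls total counts kept 99 and lost 12, and an estimated correlation kept 22 of 111. Unless a value or the setting's own construction shows it, the cause was not tested.

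With total counts, changed features numbered 1287 in P14 small RNA, 8459 in P18 small RNA (49 loci lower), 4594 in P18 piRNA-enriched small RNA and 7121 for the change of effect from P18 to P28. *Btbd18* in P18 small RNA turned from -1.39 to 0.81, and in P18 piRNA-enriched small RNA *Mir184* turned to 0.21 and *Mir29a* to 0.94. With TMM from miRNA genes there were 54 in P14 small RNA, 50 lower loci in P18 small RNA, 46 lower loci in P14 piRNA-enriched small RNA, and 2742 features and 0 lower loci in that of P18.

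Without the low-count filter the counts were 5 at P10, 351 at P14, 683 in spermatocytes, 6 in P10 and 589 in P14 small RNA, 85 for the change of effect from P10 to P18, and in piRNA-enriched small RNA 16 at P10 (10 loci lower), 376 at P14 (90 loci) and 16 loci at P18. DESeq2 gave 13 at P10, 290 at P14, 367 in P14 small RNA, 7 (all lower loci) in P10 and 175 (73 loci) in P14 piRNA-enriched small RNA, 0 lower loci in that of P18, 2782 for round spermatids against spermatocytes and 173 for P18 against P10. Tested against a 1.5-fold change, 53 remained at P14, 122 at P18, 2496 at P28, 106 in spermatocytes, 100 and 1920 in P14 and P18 small RNA, and 477 (0 lower loci) in P18 piRNA-enriched small RNA. With only the libraries compared, where fewer libraries set the spread, there were 60 at P14, 92 at P18, 46 (3 loci) and 0 (0 loci) in P10 and P14 small RNA, and 1 (1 locus), 0 (0 loci) and 785 (2 loci) in piRNA-enriched small RNA at P10, P14 and P18.

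Outside P14 small RNA with and without enrichment, replicate numbers do not pair the samples, if all same-numbered correlations must exceed 0.1. Correlations of same-numbered libraries were 0.0270 to 0.0748 at P10, -0.221 to -0.0962 at P18, -0.0186 to 0.282 in spermatocytes, -0.0133 to 0.0333 in round spermatids and 0.0882 to 0.145 in P18 small RNA. Among comparisons with 3 numbered pairs every library correlated best with its own number at P10 alone. With 2 pairs the values were 0.289 in P14 small RNA and 0.174 in P14 piRNA-enriched small RNA, so numbers may pair those libraries. With the replicate number as a block, 4 features changed at P10, 412 in spermatocytes, 416 in round spermatids (10 loci lower), 458 in P14 and 2348 in P18 small RNA (64 loci lower), and 100 in P14 piRNA-enriched small RNA, with 4 lower loci in that of P18. In P18 small RNA, knockout replicate 2 and the unnumbered heterozygous library had no partner of the same number. They therefore did not inform the blocked genotype effect there. The block kept 54 of 55 gene list calls and added 3.

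Leaving out each library in turn moved counts as follows, lower loci in brackets: 1 to 4 at P10 (4 without heterozygous replicate 3), 47 to 347 at P14 (36 to 66), 191 to 1228 at P18 (55 to 66), 5800 to 6673 at P28 (64 to 65), 24 to 427 in spermatocytes (14 to 37), 0 to 5254 in round spermatids (0 to 54), 0 to 1 in P10, 67 to 820 in P14 (44 to 106) and 2933 to 3477 in P18 small RNA (75 to 88), and 0 in P10, 0 to 1115 in P14 (0 to 102) and 3 to 2277 in P18 piRNA-enriched small RNA (0 to 26). For the changes of effect the ranges were 592 (without spermatocyte knockout replicate 1) to 3386 (without round spermatid knockout replicate 2) between cell types (15 to 45), 12 (without P18 heterozygous replicate 2) to 197 (without P18 knockout replicate 2) from P10 to P18 (5 to 13) and 2139 (without P28 heterozygous replicate 2) to 3770 from P18 to P28 (5 to 11), and for ages 7045 to 8200, 7277 to 8642 and 8220 to 9805 (41 to 60, 3 to 5 and 100 to 143). Without P10 heterozygous replicate 2 and P18 knockout replicate 1, 68 features (54 loci lower) changed in P14 and 2040 (38 loci lower) in P18 piRNA-enriched small RNA, and *Btbd18* at P18 turned from 2.38 to -0.0404 (-0.0526 without the library labelled knockout replicate 1 alone, up to 3.27 without knockout replicate 2). Over genic loci the correlation of piRNA-enriched small RNA with precursor RNA at P10 turned from -0.573 to 0.063 among loci of at least 1 CPM in both.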

Other observations

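The test on genes near *Btbd18* was chosen before its result was seen, and the other values below were drawn together after the results were seen.

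Loss of *Btbd18* left P10 testes almost untouched, took away precursor RNA and small RNA of the same intergenic piRNA loci from P14 on, and was followed by the absence of spermatid RNA. 47 loci were low at P14, P18 and P28, and 45 of them lost small RNA at P14 and 46 at P18. Of 108 genic loci, 56 of which fell from P10 to P14 in heterozygotes, 2 fell in knockout testes at P14 and 5 at P18, whereas 16 rose and 15 fell at P28 with TMM. *Piwil1* and *Tdrd6*, which serve the pachytene pathway, fell at P14 (-1.09 and -1.86), and none of 25 piRNA pathway genes passed at P18, when intergenic loci stood at a median of -1.59. The missing gain of late genes at P28 (median 0.20 log2 in knockouts against 4.61 in heterozygotes) suggests that germ cells did not complete the spermatid stages, or that their late transcripts were not made, and RNA levels cannot tell these apart. Cells purified as round spermatids from knockouts held spermatogonial RNA, so that fraction may not have contained the same cells in both genotypes. Of the 10 markers tested out of 21, 9 were higher, 6 of them without a heterozygous count. The list call was lost with an estimated correlation (adjusted p = 0.266), and leaving out any heterozygous library left no changed feature.

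Small RNA over *Tdrd6*, *Exd1* and *Rimbp3* rose at P14 and P18 while that of intergenic loci fell, and it rose in piRNA-enriched libraries of P18 as well (3.41 for *Tdrd6*). *Tdrd6* RNA itself was lower at P14 (-1.86). A feature of the opposite kind was *Chst1*, whose RNA (-3.91 at P18) and small RNA (-5.40 at P18) were both lower. It lies within 10 Mb of *Btbd18*. Its genotype effect in testes differed between P10 and P18. The core locus 2-qE1-35981 is named for the same chromosome, and its distance from *Chst1* was not tested.

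A hypothesis was that alleles of the strain in which the gene was deleted, carried along on chromosome 2, change genes around *Btbd18*. Within 10 Mb 7 of 118 tested genes were changed at P18 (5.93%) against 452 of 15050 elsewhere (3.00%), one-sided Fisher p = 0.0671, which leaves the question open. The changed genes were *Chst1* (-3.91), *Ttc30a2* (-0.99), *Zswim2* (-0.81), *Prdx6b* (-0.77), *1110051M20Rik* (-0.73), *Api5* (-0.34) and *Sestd1* (0.26), named here because of their position.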
